A study of Mus musculus with 9 samples.

How the data were processed

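Expression was measured in 9 mouse samples on Affymetrix mouse Gene 1.0 ST arrays, with 3 biological replicates in each of 3 groups: embryonic cardiomyocytes positive for an Nkx-YFP reporter, embryonic cardiac fibroblasts and adult cardiac fibroblasts. Groups and replicate numbers were taken from the sample titles. Trizol was used to extract the RNA, which was labelled with a biotin kit (Ambion MessageAmp II), per the labels' protocols. The stage of the embryos, the age and sex of the adult animals, and whether the fibroblasts had been cultured are not given in the sources used here.

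The deposited values were made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, normalizes the arrays to each other and summarizes the probes of a transcript into 1 value. The log base is not stated; the deposited values run from 2.70 to 14.20 and were read as log2, the scale that RMA gives. Genes were not centred, since the medians of the arrays lie well above 0: 7.60, 7.63 and 7.64 in the cardiomyocytes, 7.65, 7.63 and 7.63 in the embryonic fibroblasts, and 7.61, 7.61 and 7.65 in the adult fibroblasts, for replicates 1 to 3. Whether all arrays were normalized in a single run, and which genome build and annotation the authors used, is not given in the sources used here, so no coordinates are printed. RMA values hold no measure of background per probe, and differences of dim genes are compressed on this scale, so a fold is a fold between RMA values.

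Probes were named through the platform annotation. Of 28767 probes, 21776 had a single gene symbol, 1618 had several and 5373 had none. The last 2 kinds stayed unnamed and out of the tests. Symbols were updated through the Entrez identifier with the RefSeq gene table of GRCm38.p6, which held 21686 of the probes with a single symbol and changed 0 of them. Each gene was represented by its probe with the highest mean over the 9 arrays, which left 19933 genes, 993 of them with more than 1 probe. Probes of a gene were called in opposite directions for 2 genes between the embryonic groups, 1 gene between the fibroblast groups and 3 genes in the remaining comparison. Values shared in full with another probe were found for 696 probes. Besides the 9 columns of these samples, the table held 0 others.

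The log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a model with a mean for each of the 3 groups. All 9 arrays entered the fit, so that the groups share an estimate of the spread, with a median of 9.21 degrees of freedom. No filter was set on dim genes. The p-values of each comparison were adjusted by Benjamini-Hochberg over the 19933 genes, and a gene was called higher or lower at an adjusted p under 0.05. All tests were two-sided. Differences are given in log2 units with the standard error of the fit (SE), and levels as the mean ± SD of 3 arrays. Median shifts of all genes were -0.0003 between the embryonic groups, -0.04 for embryonic against adult fibroblasts and 0.06 for adult fibroblasts against cardiomyocytes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

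The 26 gene lists, the markers of 10 cell types, the tests of the comparisons and lists, the rule for naming genes and all alternatives except the one listed last below were fixed before the data were examined. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists and 3 comparisons together. Counts of members that rose or fell are given over all genes and adjusted over the list alone. Camera was also run with a correlation estimated for each list: 68 of the 108 shifts were called at the preset value and 0 with the estimate, where the lowest adjusted p was 0.0696. Limma's fry, which asks only whether the members of a list move one way on balance, was run beside it, and its values are not used here. Genes named in the text are, in each direction, the 8 with the largest difference in the main comparisons and the 5 largest in the secondary one. They had to be called, with groups that do not overlap, and predicted or unnamed loci were left out. Added to these are up to 4 called members with the largest difference in each list described, the 10 genes with the largest smaller difference among those above both other groups, and Fn1, Col1a1, Col3a1, Hbegf, Itgb1 and Nkx2-5 in any case. The genes named in any case are tied to the purpose stated for the series or known from the study. Their results are therefore not independent of the study.

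Embryonic fibroblasts enter both main comparisons, so the genes above both other groups were set beside 20 simulations of unchanged groups with the residual variances of the genes, and beside the overlap of independent lists. Alternatives were the replicate number as a block, centring each array on its median, quantile normalization, leaving out genes whose mean lay below the 30th percentile of all probes (5265 genes), the mean of all probes of a gene, only the groups compared, eBayes with trend and robust, array weights, an absolute log2 difference of at least 1, all deposited probes, and leaving out each array in turn. After the correlations between arrays had been seen, a fit without replicate 3 of both fibroblast groups was added.

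The procedure was tested on simulated data with the means and residual variances of the 19933 genes, with 66 or 67 genes changed at each of 3 sizes per comparison. For the embryonic groups it recovered 40.3% of genes changed by 0.50 log2 units, 74.6% of those changed by 1.00 and 95.5% of those changed by 2.00, with 6 false calls. For embryonic against adult fibroblasts it recovered 37.3%, 92.5% and 97.0% at these sizes with 4 false calls. For adult fibroblasts against cardiomyocytes it recovered 44.8%, 88.1% and 100% with 13 false calls. In separate simulations with no other change, the oxidative phosphorylation list shifted by 0.50 was called in each comparison, with 0 of the other 35 lists called. Shifts of other lists, and lists among many changed genes, were not tried. The noise of each simulated gene was drawn independently, so false list calls from members that vary together were not tested.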

Results

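Messenger RNA was profiled in 3 preparations of mouse heart cells, each with 3 biological replicates on separate arrays. These were embryonic cardiomyocytes carrying an Nkx-YFP reporter, which marks cells with activity of a cardiac lineage gene, embryonic cardiac fibroblasts and adult cardiac fibroblasts. Fibroblasts are the main producers of extracellular matrix in the heart. The purpose stated for the series was to find factors from fibroblasts that drive the proliferation of myocytes. A total of 19933 genes were compared, and the number of arrays limits the precision. Between arrays of the same group the median Pearson correlation over all probes was 0.994 in cardiomyocytes, 0.991 in embryonic fibroblasts and 0.970 in adult fibroblasts. Between groups it was 0.966 for the embryonic cells, 0.948 for the fibroblasts and 0.903 for adult fibroblasts and cardiomyocytes. Adult fibroblast replicate 3 stood apart, with a mean correlation of 0.970 with its own group against 0.981 for replicates 1 and 2, and an SD over probes of 1.71 against 1.83 and 1.85. Probes are not independent replicates, so these correlations describe the arrays only.

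The first comparison asked which genes embryonic fibroblasts expressed above or below embryonic cardiomyocytes. In embryonic fibroblasts 17 of 31 collagen genes, 12 of 32 cytokine genes and 14 of 30 mesenchymal transcription factors rose, beside 10 of 12 endothelial and 8 of 14 macrophage markers. Of the sarcomere genes 22 of 28 fell, as did 20 of 25 calcium handling, 26 of 35 oxidative phosphorylation and 29 of 34 mitotic genes. The shifts of these lists passed camera at the preset correlation, and the lowest adjusted p among all lists was 0.0816 with an estimated correlation. The largest rise was that of Ptgs2, the inducible prostaglandin synthase, which was 19.4-fold higher (log2 difference 4.28 ± 0.15, SE, n = 3 per group, adjusted p = 3.26e-06). The chemokine Ccl2 was 9.71-fold higher (3.28 ± 0.23) and the matrix glycoprotein Thbs1 8.97-fold higher (3.16 ± 0.18). Of the genes that were lower, Klhl31 showed the largest difference, 6.63-fold (log2 difference -2.73 ± 0.40, adjusted p = 0.00132).

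In all, 2054 genes were higher and 2212 were lower in embryonic fibroblasts, of which 521 and 492 differed by at least 2-fold. The values of the groups did not overlap for 39.1% of all genes, where chance gives 10%. Among the most increased genes were also Ch25h, a sterol hydroxylase (3.78 ± 0.27), the tachykinin precursor Tac1 (3.70 ± 0.44), the scavenger receptor Olr1 (3.39 ± 0.12), the cytokine Il1a (3.24 ± 0.40) and the cystine transporter gene Slc7a11 (3.15 ± 0.31). The most decreased genes included Ppp1r3c (-2.68 ± 0.21) and Ppp1r3a (-2.25 ± 0.23), which encode glycogen-targeting subunits of a phosphatase, and the gene of an AMP-activated kinase subunit, Prkaa2 (-2.25 ± 0.27). They also included Strip2 (-2.49 ± 0.18), Fsd2 (-2.48 ± 0.24), the cardiac transcription factor Hey2 (-2.39 ± 0.29) and the ligand gene Bmp10 (-2.30 ± 0.20). Without embryonic fibroblast replicate 2 the number of lower genes fell to 1452, and with array weights the counts rose to 3103 higher and 3362 lower. With only the embryonic groups fitted, 2611 genes were higher and 2679 lower.

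Of 31 collagens and collagen-processing enzymes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with Lox (1.55), Col14a1 (1.51), Col5a2 (1.32) and Col3a1 (1.30) showing the largest log2 differences. Col1a1 rose by a smaller amount (0.66 ± 0.13, adjusted p = 0.00612). Among matrix glycoproteins and proteoglycans 24 of 50 members rose and 1 fell (29 and 2 adjusted over the list alone), led by Thbs1 (3.16), Tnc (2.95), Dcn (2.45) and Lum (1.99). Fibronectin, encoded by Fn1, stood at 12.58 ± 0.20 (SD, n = 3) in embryonic fibroblasts and 11.11 ± 0.15 in cardiomyocytes, a 2.76-fold difference (adjusted p = 7.27e-05). For matrix proteases and their inhibitors, 14 of 27 members rose and 1 fell (15 and 1 adjusted over the list alone), including Mmp2 (1.87), Mmp13 (1.41), Plat (1.36) and Ctsk (1.24). Camera called the 3 lists at the preset correlation (adjusted p = 1.22e-09, 3.13e-11 and 5.46e-06) but not with an estimated correlation (adjusted p = 0.135, 0.107 and 0.122).

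Among integrins, the receptors for these matrix proteins, and adhesion adaptors, 10 of 32 members rose and 1 fell (12 and 1 adjusted over the list alone). In this list Itgav (1.77), Itga8 (1.66) and Itga2 (1.46) were higher and the talin gene Tln2 was lower (-1.09). Itgb1, the common integrin beta subunit, did not pass the test (0.21 ± 0.08, adjusted p = 0.0801), but it passed with array weights (adjusted p = 0.0440, over a range from 0.0440 to 0.253). Of 9 ligands of the EGF receptor family, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely Hbegf (2.15), Ereg (1.07) and the neuregulin gene Nrg1 (0.31). Hbegf, heparin-binding EGF-like growth factor, was 4.42-fold higher (adjusted p = 0.000186), at 11.84 ± 0.21 against 9.69 ± 0.13. In the FGF, IGF, PDGF, VEGF and HGF families 7 of 35 members rose and 7 fell (10 and 8 adjusted over the list alone), with Ptn (1.73) and Vegfd (1.06) higher and Angpt1 (-1.72) and Fgf13 (-1.22) lower. Ligands and antagonists of the TGF-beta and BMP families included 6 that rose and 2 that fell out of 25 (7 and 2 adjusted over the list alone). Here Bmp2 (1.37) and Tgfb1 (0.94) were higher, and Bmp10 (-2.30) and Bmp7 (-1.32) lower. Among Wnt ligands and modulators 3 of 26 members rose and 1 fell (2 and 1 adjusted over the list alone), and those were Sfrp2 (1.32), Frzb (1.05) and Dkk2 (0.51) in the upward direction and Sfrp1 in the downward one. Only the integrin list of these 5 was called by camera (adjusted p = 1.82e-05, and adjusted p = 0.0846 with an estimated correlation), while the other lists gave adjusted p = 0.143, 0.236, 0.0813 and 0.344.

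Of the cytokines and chemokines, 12 of 32 members rose and 1 fell (15 and 1 adjusted over the list alone), with Ccl2 (3.28), Ptx3 (2.56), Cxcl2 (2.35) and Cxcl10 (2.16). Complement and acute phase genes showed 5 members up and 1 down of 18 (6 and 1 adjusted over the list alone), among them C3ar1 (2.24), Serping1 (1.27), Cfi (1.18) and C1qc (0.88). The list's entry C1s was not matched to the array's C1s1, which is not counted. In the list of interferon response and antigen presentation 7 of 24 members rose and 0 fell (7 and 0 adjusted over the list alone), including Rsad2 (2.56), Ifit3 (2.23), Ifit1 (1.89) and Mx2 (1.42). The embryonic fibroblast arrays differed widely in some of these genes, with an SD of 1.35 for Cxcl10, 1.11 for Rsad2, 1.09 for Ifit1 and 0.92 for Ifit3. Macrophage markers moved with them: 8 of 14 members rose and 0 fell (9 and 0 adjusted over the list alone), such as Ctss (1.77), Mrc1 (1.47), Cd14 (1.36) and Tyrobp (1.20). Camera gave adjusted p = 1.07e-07, 0.0197, 0.000172 and 0.000122 for these 4 lists, and adjusted p = 0.0889, 0.107, 0.372 and 0.208 with an estimated correlation. The complement call was also lost without replicate 3 of both fibroblast groups (adjusted p = 0.0627, over a range from 0.00794 to 0.0627 at the preset correlation).

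Transcription factors of mesenchyme and epicardium rose in 14 of 30 cases and fell in 0 (18 and 1 adjusted over the list alone), with Foxc2 (2.37), Ebf1 (1.83), Tcf21 (1.38) and Creb3l1 (1.30). Markers of fibroblasts, 6 of the 12 also in another list, rose in 10 of 12 cases and fell in 0 (11 and 0 adjusted over the list alone). Those of the epicardium and mesothelium rose in 5 of 12 with 0 falling (10 and 0 adjusted over the list alone). Examples were Dcn (2.45), Lum (1.99), Dpt (1.53) and Pdgfra (1.51) in the former and Upk1b (1.77), Aldh1a2 (1.13) and Gpm6a (0.96) in the latter. Endothelial markers were also higher in the embryonic fibroblast arrays, where 10 of 12 rose and 0 fell (10 and 0 adjusted over the list alone), with Emcn (1.84), Cdh5 (1.83), Pecam1 (1.80) and Tek (1.61). How far endothelial or epicardial cells supplied the genes that were higher in this preparation was not tested. Smooth muscle and pericyte markers went both ways, with 3 up and 3 down of 12 (3 and 4 adjusted over the list alone). Here Rgs5 (1.41) and Pdgfrb (1.19) were higher and Cnn1 (-1.77) and Des (-1.07) lower. The adjusted p of camera was 3.16e-07, 1.21e-08, 0.000103 and 7.65e-06 for the 4 lists that rose and 0.381 for smooth muscle, and adjusted p = 0.0816, 0.0843, 0.0827 and 0.267 for those 4 with an estimated correlation.

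Most muscle genes of the fixed lists were lower in embryonic fibroblasts than in cardiomyocytes. Of the cardiac sarcomere genes 0 of 28 members rose and 22 fell (0 and 23 adjusted over the list alone), led by Myom1 (-2.18), Myoz2 (-1.90), Lmod2 (-1.88) and Actn2 (-1.86). The troponin gene Tnnt2 stood at 13.82 ± 0.06 in cardiomyocytes and at 13.38 ± 0.10 in embryonic fibroblasts, a difference that did not pass the test (-0.44 ± 0.27, adjusted p = 0.328). The arrays of these groups did not overlap in Tnnt2 (13.26 to 13.44 against 13.77 to 13.88), and its SE includes the spread of the adult arrays, with an SD of 0.68. For genes of calcium handling and ion channels, 0 of 25 members rose and 20 fell (0 and 22 adjusted over the list alone), with Gja5 (-2.05), Casq2 (-1.99), Slc8a1 (-1.95) and Ryr2 (-1.85). Cardiac transcription factors fell in 12 of 23 cases and rose in 0 (0 and 13 adjusted over the list alone), and Hey2 (-2.39), Esrrg (-1.83), Myocd (-1.66) and Smyd1 (-1.64) changed the most. Nkx2-5, the gene behind the reporter's name, had values near 8.30 ± 0.13 in cardiomyocytes and 8.25 ± 0.08 in embryonic fibroblasts, and did not pass the test (-0.05 ± 0.10, adjusted p = 0.813). Its value in adult fibroblasts was alike (8.23 ± 0.15). Whether the probe used measures the transcript was not tested, so equal Nkx2-5 RNA in these cells is not shown. Of the 12 cardiomyocyte markers, 10 of which belong to other lists as well, 9 fell and 0 rose (0 and 9 adjusted over the list alone). Camera gave adjusted p = 5.27e-15, 1.42e-13, 1.10e-07 and 1.14e-07 for the 4 lists, and adjusted p = 0.107, 0.0816, 0.0816 and 0.124 with an estimated correlation. Contractile and myofibroblast genes were divided, with 5 higher and 4 lower of 21 (6 and 4 adjusted over the list alone). Flna (1.14) rose, and Cnn1 (-1.77), Myl9 (-1.52) and Palld (-1.19) fell. That list had a median of 0.19 and a mean of -0.008, of opposite sign, and camera's direction was up (adjusted p = 0.275).

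Most energy metabolism and mitotic genes of the lists were lower in embryonic fibroblasts than in cardiomyocytes. Of the oxidative phosphorylation genes, 0 of 35 members rose and 26 fell (0 and 31 adjusted over the list alone), as in Cox7a1 (-1.97), Cox8b (-1.88) and Ndufv1 (-1.65). Fatty acid oxidation had 19 members down and 0 up of 23 (0 and 21 adjusted over the list alone), and glycolysis 13 down and 1 up of 21 (1 and 17 adjusted over the list alone). Decreases included Fabp3 (-1.70), Ppargc1a (-1.64) and Acadm (-1.54) in the former and Eno3 (-1.92) and Pgam2 (-1.57) in the latter, where Pfkfb3 was the member that rose (2.34). Genes of mitosis and the G2/M phase fell in 29 of 34 cases and rose in 0 (0 and 32 adjusted over the list alone), with Cenpf (-1.58), Hmmr (-1.46), Kif2c (-1.20) and Bub1b (-1.19). DNA replication and S phase genes fell in 10 of 31 and rose in 1 (1 and 11 adjusted over the list alone), with Rrm2 (-1.08) and Gins1 (-0.91). All 5 lists were called by camera (adjusted p = 4.68e-15, 5.75e-11, 5.10e-09, 4.15e-17 and 0.000227), and none with an estimated correlation (adjusted p = 0.124, 0.103, 0.111, 0.113 and 0.164). The list of cell cycle inhibitors and senescence genes was split, 5 up and 5 down of 20 (5 and 8 adjusted over the list alone), with Gadd45a (1.70), Plk2 (0.96) and Mdm2 (0.81) higher and Btg2 (-1.04) lower. Immediate early and heat shock genes were split as well, 6 up and 6 down of 29 (8 and 7 adjusted over the list alone), and the proto-oncogene Myc rose by 2.88 ± 0.16. Imprinted and fetal growth genes had 6 members up and 4 down of 19 (9 and 5 adjusted over the list alone). Cytosolic ribosomal protein genes had 0 up and 0 down of 26 by limma (0 and 0 adjusted over the list alone; 2 at an unadjusted p under 0.05). Camera called none of these 4 lists (adjusted p = 0.851, 0.364, 0.242 and 0.262). The ribosomal list was called after quantile normalization (adjusted p = 0.0481, over a range from 0.0481 to 0.504 at the preset correlation, and 0.626 with an estimated one).

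**Figure D1:**
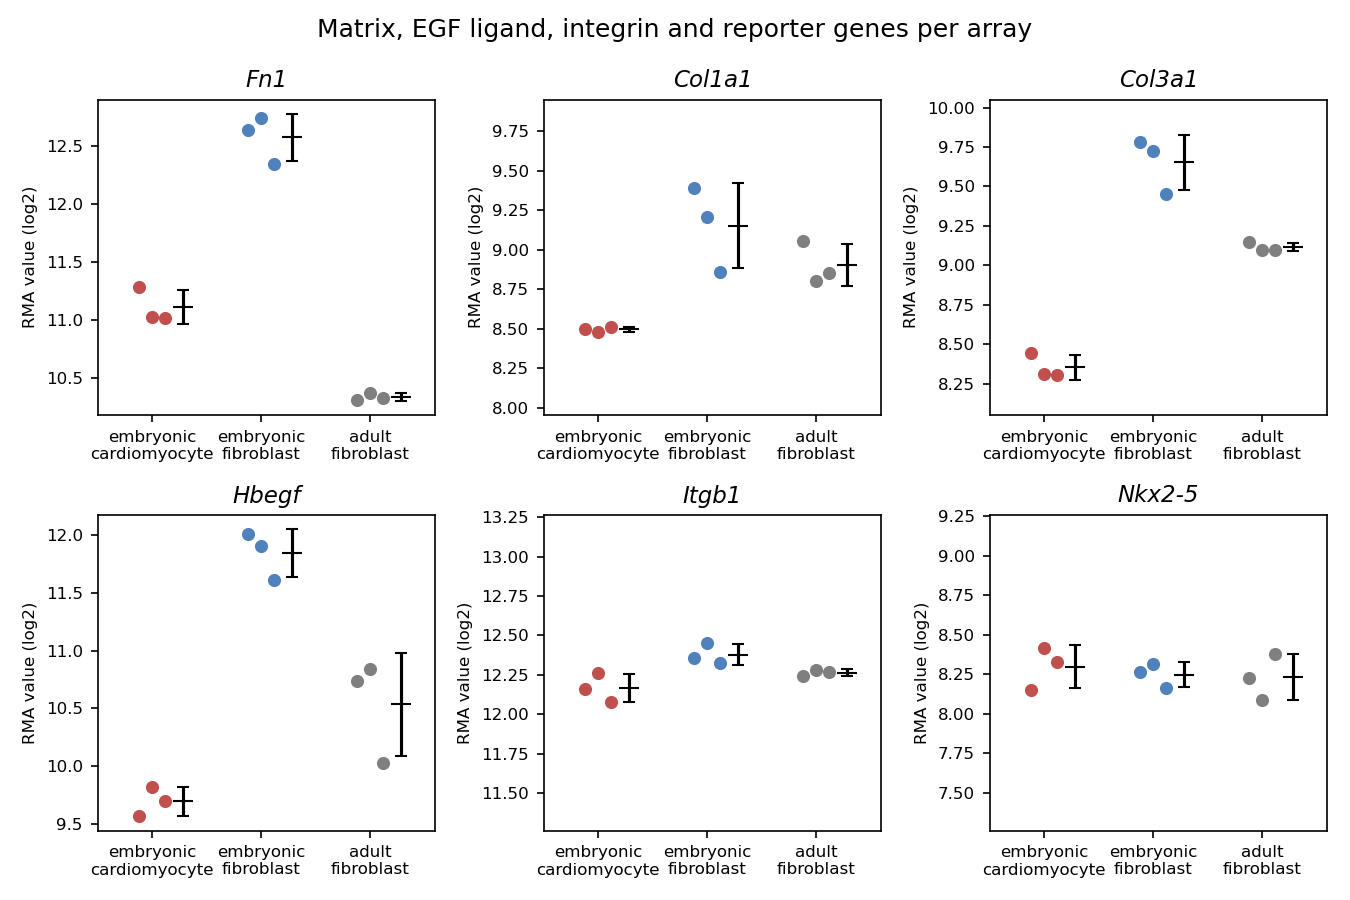
RMA values (log2) of 6 genes chosen in advance in each of the 9 arrays, with the mean ± SD of 3 arrays as a bar beside each group. The genes were chosen as tied to the purpose stated for the series or known from the study. Fn1 and Hbegf lay highest in embryonic fibroblasts (12.58 and 11.84), whereas Itgb1 and Nkx2-5 did not pass the test in any of the 3 comparisons. Whether the Nkx2-5 probe measures its transcript was not tested.

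The second comparison set embryonic against adult cardiac fibroblasts, which differ in age. Y-linked genes were low in all adult and high in all embryonic arrays, so sex, which the labels do not give, cannot be separated from age here. Xist was high in all of them (10.49 to 11.92). In embryonic fibroblasts 33 of 34 mitotic, 14 of 19 imprinted, 23 of 28 sarcomere and 30 of 35 oxidative phosphorylation genes rose, beside 11 of 12 cardiomyocyte markers. Of the cytokine genes 23 of 32 fell, as did 19 of 24 interferon, 8 of 18 complement and 13 of 27 protease genes, beside 6 of 14 macrophage markers. These list shifts passed camera at the preset correlation, and the lowest adjusted p among all lists was 0.0696 with an estimated correlation. Bex1 was 64.7-fold higher in the embryonic cells (log2 difference 6.02 ± 0.24, SE, n = 3 per group, adjusted p = 8.72e-07), and Top2a, the topoisomerase of dividing cells, was 14.8-fold higher (3.89 ± 0.17). The cytokine Il6 was 57.2-fold lower in embryonic than adult fibroblasts (-5.84 ± 0.42, adjusted p = 1.65e-05), and the chemokine Cxcl5 was 32.4-fold lower (-5.02 ± 0.13).

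Altogether 2232 genes were higher and 1662 lower in the embryonic fibroblasts, 730 and 501 of them by at least 2-fold, and 33.0% of genes had groups without overlap, where chance gives 10%. Further genes with the largest increases were Hbb-y, an embryonic globin (4.80 ± 0.14), Bex4 (4.38 ± 0.20), and the muscle genes Actc1 (4.77 ± 0.20), Smpx (4.40 ± 0.32), Tnnc1 (18.4-fold) and Myh7 (3.95 ± 0.19). The largest decreases were also found for ceruloplasmin, Cp (-4.91 ± 0.13), the interferon-inducible Ifi205 (-4.37 ± 0.50), the complement protease gene C1s1 (-4.35 ± 0.31), lubricin, Prg4 (-4.15 ± 0.26), the sodium channel gene Scn7a (-4.02 ± 0.24) and the chemokine Cxcl9 (-3.93 ± 0.60). With array weights the number of lower genes rose to 2519. With only the fibroblast groups fitted, 1778 genes were higher and 1216 lower.

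Most cell division genes of the lists were higher in the embryonic fibroblasts. Of the genes of mitosis and G2/M, 33 of 34 members rose and 0 fell (34 and 0 adjusted over the list alone), including Top2a (3.89), Bub1 (3.82), Anln (3.23) and Kif4 (3.22). For DNA replication and S phase, 23 of 31 members rose and 0 fell (25 and 0 adjusted over the list alone), with Prim1 (2.86), E2f8 (2.71), Mcm4 (1.90) and Rrm2 (1.87). Imprinted and fetal growth genes rose in 14 of 19 cases and fell in 1 (15 and 1 adjusted over the list alone). The growth factor gene Igf2 was 10.4-fold higher, at 11.78 ± 0.16 against 8.41 ± 0.16, and Mest (3.13), Gpc3 (2.97) and Cdkn1c (2.52) were higher too. The list of cell cycle inhibitors and senescence genes had 4 members up and 2 down of 20 (4 and 2 adjusted over the list alone), with Cdkn1c (2.52), Rbl1 (1.31) and Glb1 (0.75) up and Gadd45a (-0.58) down. Camera gave adjusted p = 1.73e-36, 2.15e-16 and 6.02e-17 for the first 3 lists, and adjusted p = 0.0816, 0.0816 and 0.0696 with an estimated correlation. The inhibitor list, whose median (-0.13) and mean (0.07) differed in sign, was not called (adjusted p = 0.782).

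Most sarcomere and oxidative phosphorylation genes were higher in embryonic than in adult fibroblasts, and cardiomyocyte markers moved with them, with 11 of 12 up and 0 down (11 and 0 adjusted over the list alone). Tnnt2 stood at 13.38 ± 0.10 in embryonic and 9.83 ± 0.68 in adult fibroblasts (adjusted p = 2.42e-05). Of the sarcomere genes 23 of 28 members rose and 0 fell (24 and 0 adjusted over the list alone), with Actc1 (4.77), Smpx (4.40), Tnnc1 (18.4-fold) and Myh7 (3.95) the largest. The calcium and ion channel list had 16 up and 1 down of 25 (16 and 1 adjusted over the list alone), as for Pln (2.79), Ryr2 (2.58), Popdc2 (2.19) and Casq2 (2.02). Cardiac transcription factors had 12 up and 1 down of 23 (12 and 1 adjusted over the list alone), as for Ankrd1 (3.22), Prox1 (1.81), Hey2 (1.26) and Myocd (1.10). Nkx2-5 did not differ past the threshold (0.02 ± 0.10, adjusted p = 0.935). Contractile and myofibroblast genes rose in 10 of 21 cases and fell in 1 (13 and 1 adjusted over the list alone), among them Acta2 (2.59), Cnn1 (2.22), Myl9 (2.08) and Myh10 (1.69). Of the oxidative phosphorylation genes 30 of 35 members rose and 0 fell (32 and 0 adjusted over the list alone), with Cox7a1 (2.27), Ndufa9 (1.91) and Cox8b (1.80). In fatty acid oxidation 12 of 23 members rose and 3 fell (12 and 3 adjusted over the list alone), where Fabp3 (2.39) and Ppargc1a (2.18) were higher and the fatty acid receptor gene Cd36 was lower (-2.01). In glycolysis 12 of 21 members rose and 2 fell (14 and 2 adjusted over the list alone), where Ldhb (2.76) and Pgam2 (2.74) were higher and Hk2 was lower (-2.23). Camera's adjusted p for these lists, in the order given, was 8.54e-15, 6.52e-24, 4.30e-10, 9.08e-05, 2.72e-06, 7.01e-19, 0.000222 and 2.67e-07, and adjusted p = 0.0816, 0.0816, 0.0984, 0.119, 0.107, 0.107, 0.265 and 0.129 with an estimated correlation. Most oxidative phosphorylation, fatty acid oxidation and glycolysis genes were also lower in embryonic fibroblasts than in cardiomyocytes. Myocyte RNA in the embryonic fibroblast arrays may contribute to their rise over adult fibroblasts, which was not tested for these metabolic lists.

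Of 32 cytokines and chemokines, 23 fell and 0 rose (0 and 26 adjusted over the list alone), with Il6 (-5.84), Cxcl5 (-5.02), Cxcl9 (-3.93) and Ccl8 (-3.20). Interferon response and antigen presentation genes fell in 19 of 24 cases and rose in 0 (0 and 23 adjusted over the list alone), including Rsad2 (-2.44), Ifit1 (-2.31), Ifit3 (-2.19) and Oasl2 (-2.17). For complement and acute phase genes, 2 of 18 members rose and 8 fell (2 and 9 adjusted over the list alone), and Cp (-4.91), Serping1 (-3.01) and C7 (-2.27) were lower while Cfi was higher (1.31). C1s1 (-4.35), held by the list under the name C1s, was not matched and is not in these counts. Macrophage markers were also lower in the embryonic than in the adult arrays, 6 of 14 falling and 0 rising (0 and 6 adjusted over the list alone), with Ptprc (-2.09), Cd14 (-1.67), Lyz2 (-1.41) and Cd68 (-1.10). Immediate early and heat shock genes had 1 up and 7 down of 29 (1 and 9 adjusted over the list alone), such as Fosl1 (-1.54), Hspa1a (-1.23) and Dusp1 (-0.75). Camera gave adjusted p = 3.78e-15, 6.65e-11, 0.000982, 0.000566 and 0.153 for these 5 lists, and adjusted p = 0.0816, 0.146, 0.0816 and 0.261 for the first 4 with an estimated correlation. The immediate early list was called without adult fibroblast replicate 3 (adjusted p = 0.0270), after quantile normalization (adjusted p = 0.00878) and without replicate 3 of both fibroblast groups (adjusted p = 0.00742). Its adjusted p ranged from 0.00742 to 0.498 at the preset correlation and was 0.618 with an estimated one.

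Among matrix glycoproteins and proteoglycans 7 of 50 members rose and 19 fell (9 and 22 adjusted over the list alone). Of these, Mfap5 (-3.74), Lama2 (-2.83) and Prelp (-2.80) were lower in the embryonic cells and the fetal fibrillin gene Fbn2 was higher (2.76). Fn1 was 4.73-fold higher in embryonic than adult fibroblasts (adjusted p = 2.49e-06). For matrix proteases and inhibitors, 1 of 27 members rose and 13 fell (1 and 15 adjusted over the list alone), with Mmp3 (-3.04), Adamts5 (-2.87), Mmp13 (-2.17) and Fap (-1.99). The collagen list was divided, 5 up and 4 down of 31 (5 and 7 adjusted over the list alone), with P4ha3 (1.29) and Col12a1 (1.14) higher and Pcolce2 (-3.12) and Col8a1 (-1.67) lower. Col3a1 was higher (0.54 ± 0.10, adjusted p = 0.00366), while Col1a1 missed the threshold (0.25 ± 0.13, adjusted p = 0.235) and passed it without embryonic fibroblast replicate 3 (adjusted p = 0.0331, over a range from 0.0331 to 0.553). Camera called the glycoprotein and protease lists (adjusted p = 0.00604 and 1.20e-05, and adjusted p = 0.422 and 0.124 with an estimated correlation) and not the collagens (adjusted p = 0.975).

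Among ligands and receptors, the list of EGF receptor family ligands had 2 members up and 1 down of 9 (2 and 1 adjusted over the list alone). Hbegf was 2.47-fold higher (adjusted p = 0.00165), Nrg1 was higher (0.55) and Ereg was lower (-1.21). In the FGF, IGF, PDGF, VEGF and HGF families 8 of 35 members rose and 10 fell (10 and 12 adjusted over the list alone), with Igf2 (3.37) and Ptn (2.57) higher and Fgf7 (-2.74) and Pgf (-1.90) lower. The TGF-beta and BMP list had 1 up and 2 down of 25 (1 and 1 adjusted over the list alone), namely Bmp5 (1.70), Inhba (-1.21) and Tgfb2 (-0.61). The Wnt list had 5 up and 2 down of 26 (5 and 3 adjusted over the list alone), with Sfrp2 (1.13) and Sfrp1 (0.75) up and Frzb (-1.76) and Sfrp4 (-1.12) down. Of the integrins and adaptors 7 of 32 members rose and 3 fell (10 and 5 adjusted over the list alone), with Itga6 (1.66) and Itga8 (1.39) higher and Sdc2 (-1.29) and Cd44 (-1.01) lower, while Itgb1 did not pass the test (0.11 ± 0.08, adjusted p = 0.347). Camera called none of the 5 lists (adjusted p = 0.364, 0.736, 0.767, 0.364 and 0.0568), and the median (0.01) and mean (-0.02) of the FGF list differed in sign. The integrin list was called in 5 of 14 alternatives at the preset correlation and not with an estimated one (adjusted p = 0.304). Among the 5 were the fits without cardiomyocyte replicate 3, embryonic fibroblast replicate 3 or adult fibroblast replicate 2 (adjusted p = 0.0472, 0.0213 and 0.0254, over a range from 0.0213 to 0.215 at the preset correlation). The others were the replicate block (adjusted p = 0.0336) and median centring (adjusted p = 0.0473).

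Markers of fibroblasts were lower in the embryonic than in the adult preparation, 9 of 12 falling and 1 rising (2 and 9 adjusted over the list alone), with Gsn (-2.92), Ddr2 (-2.22), Dpt (-2.21) and Lum (-2.00). Mesenchymal and epicardial transcription factors had 2 up and 7 down of 30 (2 and 8 adjusted over the list alone), with Prrx1 (-1.69), Tcf21 (-1.38), Ebf2 (-1.05) and Meox2 (-0.98). Epicardial and mesothelial markers were higher in the embryonic cells, 8 of 12 rising and 0 falling (8 and 0 adjusted over the list alone), including Upk1b (2.16), Gpm6a (1.89), Krt18 (1.20) and Krt19 (1.16). Endothelial markers had 2 up and 1 down of 12 (2 and 1 adjusted over the list alone), namely Emcn (1.29), Tek (0.65) and Cldn5 (-0.87). Cdh5, the cadherin of endothelium, ranged from 10.36 to 11.95 over the adult arrays. Smooth muscle and pericyte markers had 4 up and 2 down of 12 (4 and 2 adjusted over the list alone), with Acta2 (2.59), Cnn1 (2.22) and Mcam (1.64) higher and Rgs5 (-2.29) lower. Adipocyte markers had 0 up and 2 down of 8 (0 and 2 adjusted over the list alone), both decreases being Fabp4 (-1.66) and Pparg (-1.03). Neural crest and Schwann markers had 0 up and 1 down of 7 (0 and 1 adjusted over the list alone), the decrease being Cdh19 (-2.52). Lymphocyte markers had 0 up and 0 down of 9 (0 and 0 adjusted over the list alone; 2 at an unadjusted p under 0.05 in limma). Ribosomal protein genes rose in 4 of 26 cases and fell in 0 (4 and 0 adjusted over the list alone), among them Rpl14 (0.94), Rpl10a (0.35) and Rpl22 (0.32).

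Camera called the fibroblast, epicardial, ribosomal and smooth muscle lists in the comparison of fibroblasts (adjusted p = 0.000218, 8.14e-07, 7.01e-05 and 0.0471, and adjusted p = 0.150, 0.0816, 0.127 and 0.304 with an estimated correlation). The call of the smooth muscle list was lost in 9 of 14 other alternatives, among them leaving out cardiomyocyte replicate 1, 2 or 3, embryonic fibroblast replicate 1 or adult fibroblast replicate 3 (adjusted p = 0.0518, 0.0556, 0.0519, 0.0582 and 0.147, over a range from 0.0223 to 0.157), and that of the ribosomal list after quantile normalization (adjusted p = 0.0512, over a range from 8.91e-06 to 0.0512). Lists of mesenchymal factors, endothelial, adipocyte, neural crest and lymphocyte markers were not called (adjusted p = 0.261, 0.0568, 0.127, 0.162 and 0.682). The endothelial list was called in 5 of 14 alternatives at the preset correlation and not with an estimated one (adjusted p = 0.621). Among the 5 were the fits without cardiomyocyte replicate 1, embryonic fibroblast replicate 3 or adult fibroblast replicate 2 (adjusted p = 0.0474, 0.0123 and 0.000575, over a range from 0.000575 to 0.560 at the preset correlation). The replicate number as a block ended the call of the smooth muscle list (adjusted p = 0.0685) and gave one for the endothelial list (adjusted p = 0.0313).

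**Figure D2:**
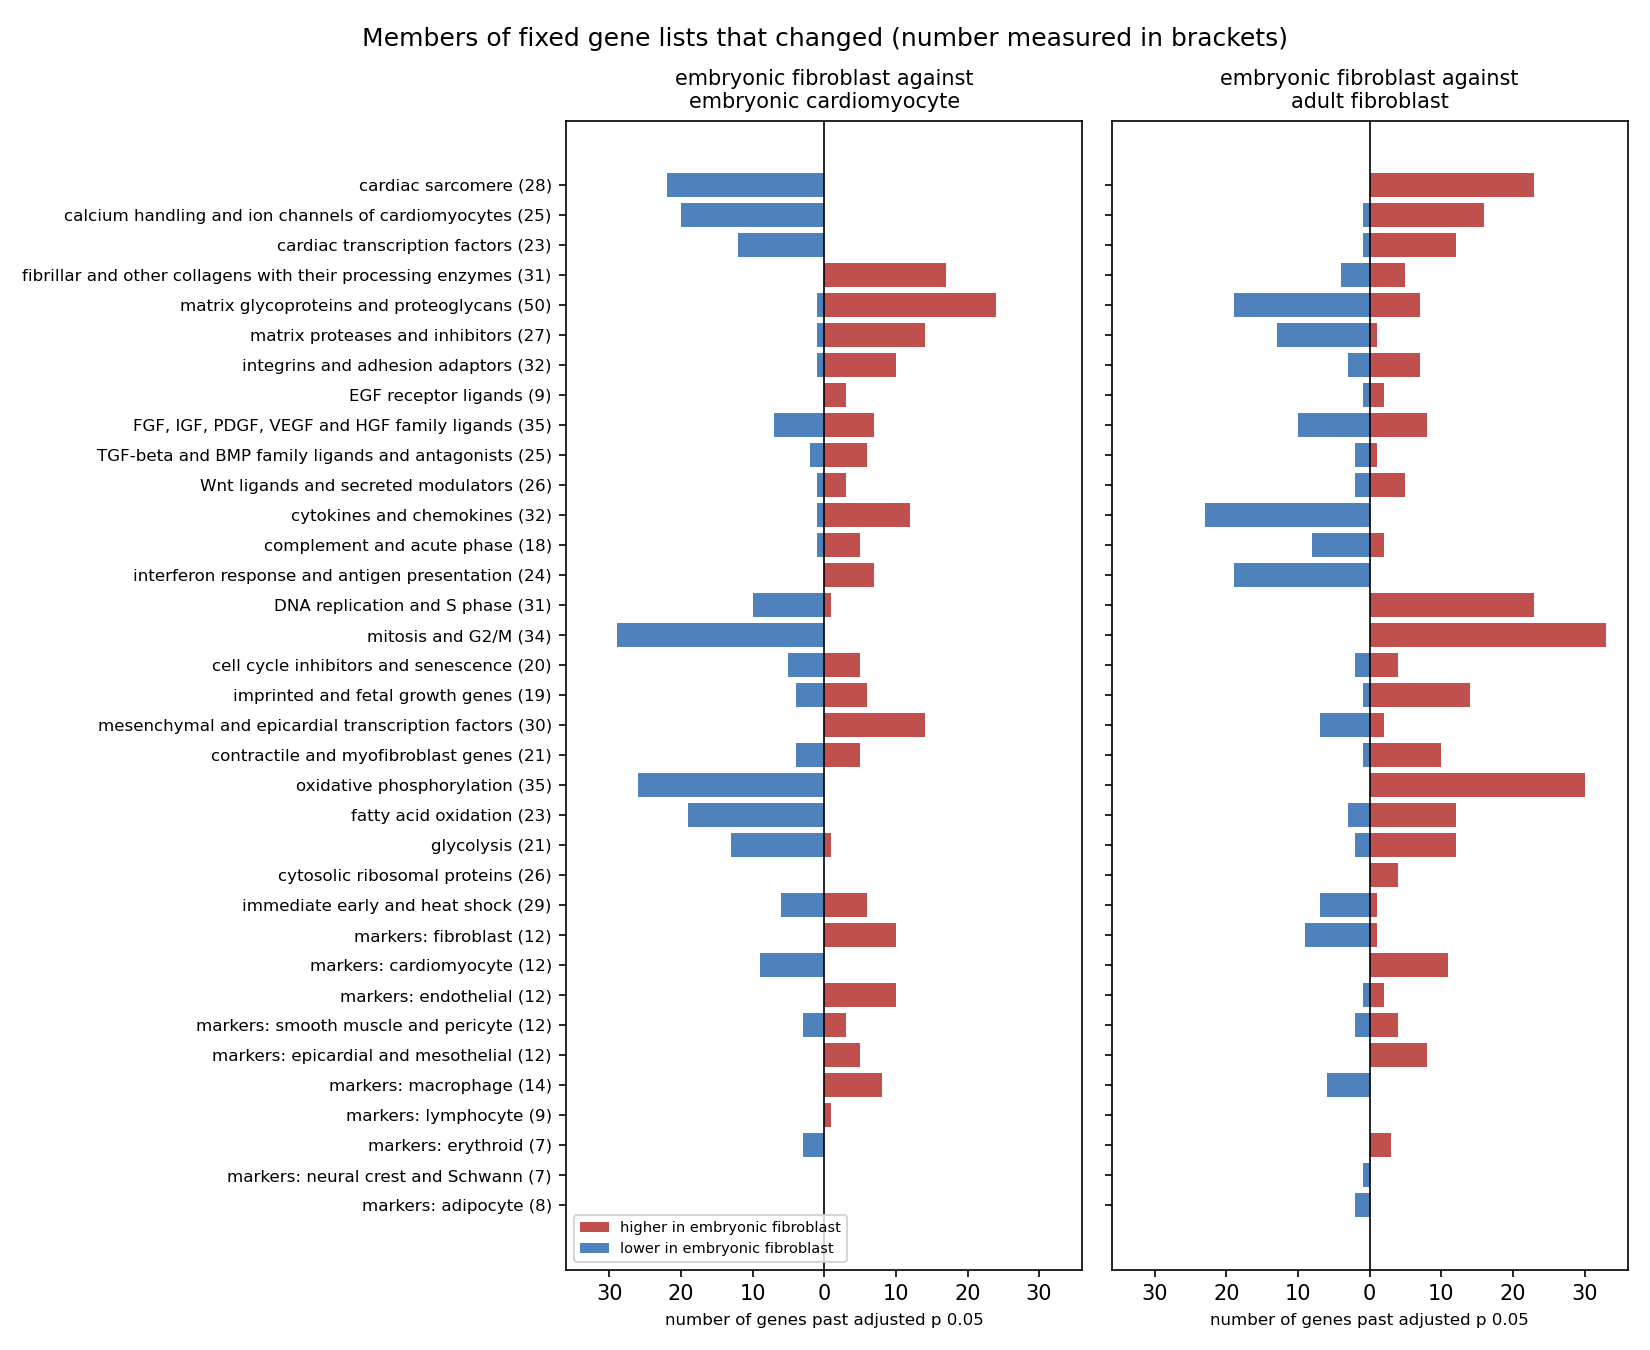
Number of members of each gene list and marker list that were higher (right, red) or lower (left, blue) in embryonic fibroblasts at an adjusted p under 0.05, against cardiomyocytes on the left panel and adult fibroblasts on the right panel, with the number measured in brackets. Sarcomere genes fell in 22 of 28 cases on the left panel and rose in 23 of 28 on the right one.

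The series sought factors made by embryonic fibroblasts, so genes above both other groups were counted. There were 362 such genes, 52 of them at least 2-fold above each group. Fabp7, a fatty acid binding protein gene, was 6.48-fold above cardiomyocytes and 6.60-fold above adult fibroblasts. The heparin-binding growth factor gene Ptn was 3.31-fold and 5.93-fold above them (1.73 ± 0.14 and 2.57 ± 0.14), and Stc1, which encodes the secreted hormone stanniocalcin, 4.78-fold and 3.38-fold. The other genes with the largest smaller difference were Klhl6 (2.04 against cardiomyocytes and 2.99 against adult fibroblasts), the peptidase gene Dpp4 (1.80 and 1.96), Upk1b (1.77 and 2.16), Klhl4 (1.76 and 3.37), Nrk (1.68 and 3.81) and the mucin gene Muc16 (1.65 and 2.10). Sprr1a was also among these 10 genes, at 9.95 ± 0.10 in embryonic fibroblasts, 7.95 ± 0.22 in cardiomyocytes and 8.22 ± 0.32 in adult fibroblasts. Fn1, Hbegf and Col3a1 belonged to the 362 genes, and Col1a1, Itgb1 and Nkx2-5 did not. Because these genes were chosen partly from knowledge of the study, their place here is not independent of it. Of the cell type markers, 4 of 12 epicardial and mesothelial (Upk1b, Gpm6a, Krt18 and Lrrn4), 2 of 12 endothelial (Emcn and Tek) and 1 of 12 fibroblast markers (Col3a1) were above both groups. Of the 14 macrophage markers 0 were. Whether endothelial, epicardial or other cells in the embryonic fibroblast preparation supplied any of the 362 genes was not tested. The genes are therefore not shown to be made by fibroblasts. Outside the lists, the endothelial genes Ramp2 and Clec14a and the myeloid genes Aif1 and Clec7a were above both groups, and they were picked after their values were seen. The mesothelial genes Upk1b and Muc16 stood at 8.80 ± 0.46 and 7.98 ± 0.54 in embryonic fibroblasts, where the medians of the arrays were 7.63 to 7.65.

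Lists of the same sizes drawn independently would share 230 genes, and simulated unchanged groups shared 0 on average at the adjusted threshold and 129 at an unadjusted p under 0.05, where 653 were observed. The simulation held no group differences, so an adjusted count near 0 follows from its setting. It cannot give the overlap that shared arrays produce among groups that differ. Both comparisons use the same 3 embryonic fibroblast arrays, which are too few to split, so part of the excess over independent lists may come from the shared arrays. Without embryonic fibroblast replicate 2 the count was 237, with array weights it was 592, and without replicate 3 of both fibroblast groups it was 528. Genes below both other groups numbered 92, where independent lists would share 184. In 1485 genes called in both comparisons the embryonic fibroblasts lay between the other groups.

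The remaining comparison, of adult fibroblasts with embryonic cardiomyocytes, differs in both cell type and age, and it gave the most calls. Adult fibroblasts had 3465 genes higher and 3626 lower, 1153 and 1495 of them by at least 2-fold, and 45.9% of genes had groups without overlap, where chance gives 10%. Il6 was 140-fold higher (log2 difference 7.13 ± 0.42, SE, n = 3 per group, adjusted p = 1.64e-06), Ptgs2 68.1-fold higher (6.09 ± 0.15) and the hyaluronan-binding gene Tnfaip6 47.2-fold higher (5.56 ± 0.20). The interferon-inducible Ifi203 (5.76 ± 0.37) and Ifi205 (5.35 ± 0.50) followed. Bex1 was 132-fold lower (-7.04 ± 0.24, adjusted p = 1.60e-07), and the other largest decreases were Hbb-y (-6.24 ± 0.14), Smpx (-5.90 ± 0.32), Bex4 (-5.65 ± 0.20) and Myh7 (-5.52 ± 0.19). Fn1 was lower in adult fibroblasts than in cardiomyocytes (-0.78 ± 0.11, adjusted p = 0.000522), whereas Col3a1 (0.76 ± 0.10, adjusted p = 0.000183) and Hbegf (0.84 ± 0.20, adjusted p = 0.00927) were higher. Col1a1 was higher as well (0.41 ± 0.13, adjusted p = 0.0355), a call that was lost when cardiomyocyte replicate 1, 2 or 3, embryonic fibroblast replicate 2 or adult fibroblast replicate 1 was left out (adjusted p = 0.0899, 0.0944, 0.0771, 0.0529 and 0.117). Itgb1 (0.10 ± 0.08, adjusted p = 0.362) and Nkx2-5 (-0.07 ± 0.10, adjusted p = 0.656) did not pass the test, though Itgb1 did after quantile normalization (adjusted p = 0.0147, over a range from 0.0147 to 0.657).

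In adult fibroblasts against cardiomyocytes, sarcomere genes fell in 26 of 28 cases (0 and 26 adjusted over the list alone), oxidative phosphorylation genes in 34 of 35 (0 and 35 adjusted over the list alone) and mitotic genes in 34 of 34 (0 and 34 adjusted over the list alone), with 0 rising in each. Examples were Ttn (-5.19), Cox7a1 (-4.25) and Ect2 (-4.19). Cytokines and chemokines rose in 26 of 32 cases (27 and 0 adjusted over the list alone) and interferon response and antigen presentation genes in 23 of 24 (24 and 0 adjusted over the list alone), with 0 falling, as for Cxcl2 (4.99) and Ifit3 (4.43). Macrophage markers rose beside them, in 12 of 14 cases (13 and 0 adjusted over the list alone), among them Cd14 (3.03) and Ptprc (2.84). Endothelial markers rose in 6 of 12 cases and fell in 0 (6 and 0 adjusted over the list alone), such as Cdh5 (1.44) and Pecam1 (1.36). Erythroid markers rose in 0 of 7 and fell in 3 (0 and 3 adjusted over the list alone), such as Hbb-y (-6.24) and Hba-x (-2.97). Camera called the endothelial and erythroid lists (adjusted p = 0.0172 and 0.00779), and gave adjusted p = 0.525 and 0.124 with an estimated correlation. The endothelial call was lost without adult fibroblast replicate 2 (adjusted p = 0.0904, over a range from 0.000379 to 0.0904), and the erythroid call when dim genes were left out (adjusted p = 0.0632, over a range from 0.00480 to 0.0632). Fibroblast markers rose in 12 of 12 cases (12 and 0 adjusted over the list alone), with Dcn at 13.49 ± 0.07 in adult fibroblasts and 9.43 ± 0.50 in cardiomyocytes. Camera gave adjusted p = 1.58e-22, 9.21e-21, 1.36e-29, 1.08e-13, 6.42e-10, 7.54e-06 and 1.72e-08 for the sarcomere, oxidative phosphorylation, mitotic, cytokine, interferon, macrophage and fibroblast lists, and adjusted p = 0.0816, 0.103, 0.0816, 0.0816, 0.158, 0.150 and 0.0843 with an estimated correlation. Median and mean differed in sign for the EGF receptor family ligands (-0.01 and 0.28) and the list of cell cycle inhibitors and senescence genes (0.11 and -0.11), which camera did not call (adjusted p = 0.873 and 0.471).

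**Figure D3:**
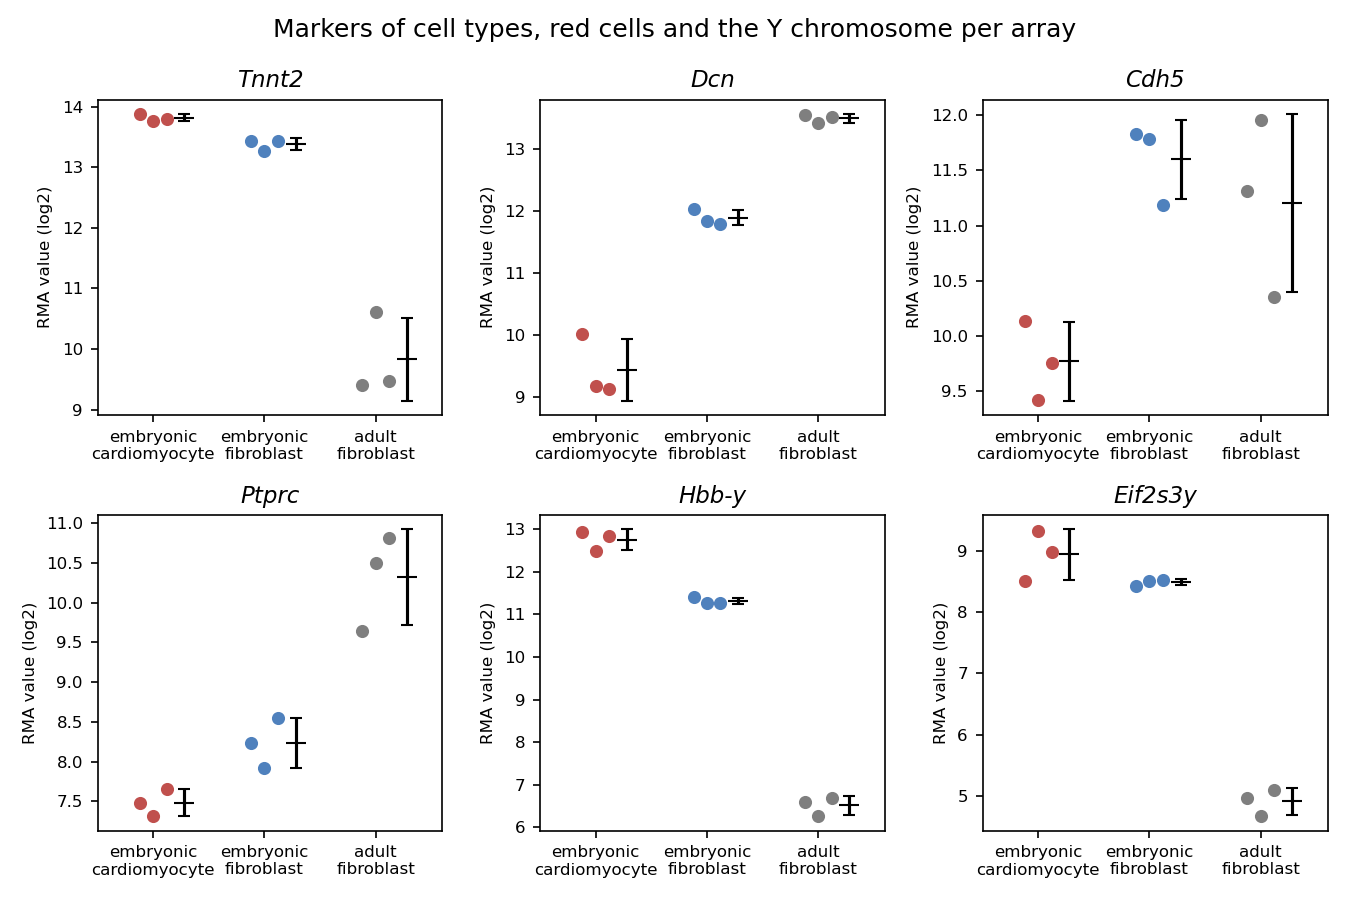
RMA values (log2) of 6 marker genes in each of the 9 arrays, with the mean ± SD of 3 arrays as a bar beside each group. Tnnt2 marks cardiomyocytes, Dcn fibroblasts, Cdh5 endothelium, Ptprc leukocytes, Hbb-y embryonic red cells and Eif2s3y the Y chromosome; the Y-linked gene lay between 4.67 and 5.10 in the adult arrays and between 8.43 and 9.33 in the embryonic arrays.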

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

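The fit without replicate 3 of both fibroblast groups was chosen after the data had been seen. Of 1517 values under the alternatives, 1502 kept their side of the threshold, 11 lost the call and 4 gained it. They stem from 80 named values: the largest differences, the largest among genes above both other groups, and the genes named in any case. Members named only from the lists were not run. A change of direction was counted only for values called in the main or the alternative fit, where it occurred in 0. Of 1620 list shifts, 1519 kept their side of the threshold, 85 lost the call, 68 of them through an estimated correlation, and 16 gained it. By the same rule 0 list shifts reversed. Leaving out dim genes removed 3 of the 80 named values, which have no result there.

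Array weights raised the genes higher and lower in embryonic fibroblasts than in cardiomyocytes to 3103 and 3362, those lower than in adult fibroblasts to 2519, and those above both groups to 592; the cause was not tested. Adult fibroblast replicate 3 had the lowest weight, 0.215. Fitted with only the groups compared, the embryonic groups gave 2611 genes higher and 2679 lower in embryonic fibroblasts. The fibroblast groups gave 1778 and 1216, and adult fibroblasts against cardiomyocytes 3008 and 3355. These counts lay above the main ones for the embryonic groups and below them in both comparisons with adult fibroblasts, whose arrays varied most. Requiring a log2 difference of at least 1 left 521 and 492 genes between the embryonic groups, 730 and 501 between the fibroblasts, 1153 and 1495 between adult fibroblasts and cardiomyocytes, and 52 above both groups, since this is a stricter criterion.

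With each array left out in turn, embryonic fibroblasts had 1448 to 2720 genes higher and 1452 to 2830 lower than cardiomyocytes, and 1779 to 2476 higher and 1188 to 2251 lower than adult fibroblasts. Adult fibroblasts had 2821 to 3846 higher and 3063 to 3790 lower than cardiomyocytes, and 237 to 434 genes lay above both groups. The counts 1452 and 237 came without embryonic fibroblast replicate 2, and the highest count of each result came without adult fibroblast replicate 3. Without replicate 3 of both fibroblast groups, 2751 and 2904, 2340 and 2130, 3942 and 3852, and 528 genes were called in the same order.

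Whether equal replicate numbers mark paired samples was not settled. Of 9 pairs of arrays with the same number, 3 had residuals correlated above 0.1, as did 3 of 18 other pairs. The correlations ran from -0.195 to 0.198 and from -0.220 to 0.191. Residuals within a group depend on each other, so this check cannot exclude pairing. With the number as a block, 2059 and 2147 genes differed between the embryonic groups. The share of calls that were higher in embryonic than adult fibroblasts was 57.3%, and 54.2% after median centring and 51.7% after quantile normalization. Background per probe is not part of RMA values, so signal over background was not examined here. Differences of dim genes are the least certain, and 5265 genes had a mean below the level of 6.91 at the 30th percentile.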

Other observations

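The tests of cardiac muscle transcripts and of leukocyte RNA given here were chosen after the result was seen.

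Y-linked genes were low in all adult fibroblast arrays. Eif2s3y stood at 8.94 ± 0.41 (SD, n = 3) in cardiomyocytes, 8.49 ± 0.05 in embryonic fibroblasts and 4.91 ± 0.22 in adult fibroblasts, and Uty was higher in embryonic than adult fibroblasts by 2.57 ± 0.16. Xist was lower in embryonic than adult fibroblasts (-0.77 ± 0.17, adjusted p = 0.0109). It ranged from 10.49 to 11.16 over the arrays of both embryonic groups and from 11.54 to 11.92 over the adult ones. The embryonic arrays thus held both Xist and Y-linked RNA. The sex-linked list had 3 members up and 1 down of 4 between the fibroblasts (3 and 1 adjusted over the list alone; camera adjusted p = 0.00433, and adjusted p = 0.119 with an estimated correlation). Effects of sex and of age on other genes cannot be separated in these comparisons. Embryonic globins were highest in the cardiomyocyte arrays, with Hbb-y at 12.76 ± 0.24, 11.32 ± 0.07 and 6.52 ± 0.23 in cardiomyocytes, embryonic and adult fibroblasts. Of 7 erythroid markers, 3 fell in embryonic fibroblasts against cardiomyocytes (0 and 3 adjusted over the list alone) and 3 rose against adult fibroblasts (3 and 0 adjusted over the list alone). Camera gave adjusted p = 0.0117 and 0.00866, and adjusted p = 0.129 and 0.124 with an estimated correlation. The former call was also lost when dim genes were left out (adjusted p = 0.0774, over a range from 0.00529 to 0.0774).

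Cardiac muscle transcripts in the embryonic fibroblast arrays may come from myocyte RNA mixed in at a single share. Over 31 myocyte genes the embryonic fibroblasts reached a median of 32.4% of the cardiomyocyte excess over the adult fibroblast level on the linear scale, from 12.1% to 79.9%, with the highest shares in bright genes such as Myl2, Actc1 and Tnnt2, which were picked after their values were seen. The SD of the log2 share over genes was 2.59 times the standard error of a gene in all 31 genes and 1.76 times in 16 genes of middle brightness, where a bound of 2 was set for both. A single share is therefore not excluded, and saturation of the brightest probes, expression of these genes in embryonic fibroblasts themselves and age stay open.

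Mitotic genes of the embryonic fibroblasts lay between the other groups. Over 33 genes they reached a median of 49.3% of the cardiomyocyte excess over the adult fibroblast level, 16.9 percentage points above the myocyte genes (95% bootstrap interval over genes 9.20 to 25.9). With no baseline subtracted, a test added after the first was seen, the difference was 20.8 percentage points (15.3 to 28.4). With the adult level taken as the fibroblasts' own level, the first difference goes against myocyte RNA as the whole source of the mitotic transcripts in the group means. Its interval treats genes as independent and holds no spread between arrays. Most cardiomyocyte markers were lowest in embryonic fibroblast replicate 2 and highest in replicate 3, as for Pln (10.46 and 11.82) and Myh7 (10.55 and 11.41). Myocyte RNA as the whole source is therefore not excluded. The difference with no baseline adds nothing to the first. Myocyte genes were required to lie further above the adult level than mitotic genes were, which by itself raises the mitotic share when nothing is subtracted. Age stays open, as untested.

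Cytokine and interferon genes were higher in adult than embryonic fibroblast arrays, where leukocyte RNA may contribute. The median adult minus embryonic difference was 0.55 for 14 macrophage markers, 2 of them also in another list, 1.57 for the cytokine list and 1.15 for the interferon list. Macrophage markers differed from the interferon list by -0.60 (95% bootstrap interval over genes -1.46 to -0.01) and from the cytokines by -1.03 (-1.69 to 0.01), and the latter interval includes 0. The intervals treat genes as independent and hold no spread between arrays. The abundant macrophage gene Lyz2 stood at 8.16 ± 0.03 in embryonic and 9.57 ± 0.79 in adult fibroblasts. Leukocyte RNA as the whole source cannot be told apart from a response of the fibroblasts, and age stays open as well.

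Other splits of the 6 arrays of each comparison were fitted with those arrays alone. The real split called 5290 genes between the embryonic groups, 2994 between the fibroblasts and 6363 between adult fibroblasts and cardiomyocytes, and the highest of the other splits called 0 in each case. In each comparison 1 of the 10 splits, the real one, gave as many genes, and 10 splits cannot give a share under 0.05. Every other split has arrays of both labelled groups on each side, so the real differences add to its spread. Its count of 0 therefore does not bear on chance. For the genes above both other groups, 4 of 100 splits of the 9 arrays, the real one included, gave as many as the real 362, and the highest other gave 1436. That split is the real grouping with the adult fibroblasts in place of the embryonic ones, and the 2 others with any genes set all arrays of a labelled group against mixtures of the rest, which points to the structure of the groups. The remaining 96 splits gave 0 genes. Genes were called only in splits whose first group was a whole labelled group, so the share of splits does not bear on chance for this count.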
